A study of Oryza sativa with 2 samples.

How the data were processed

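Small RNA sequencing was done on total RNA from young panicles of japonica rice, size-selected on a gel at 18 to 35 nt, per the labels' protocols. The series had 2 libraries, 1 control and 1 DES1 mutant, and each deposited file held reads of 24 nt only. Bowtie is named without a version in the submitters' processing notes, and its settings and the genome build are not given in the sources used here. Coordinates are therefore given as deposited, 1-based, with no build name.

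Each deposited file had 1 line per alignment of a distinct 24-nt sequence, with 10832872 lines in the control and 1151562 in the mutant. A line gave the position and strand, the number of genome alignments of the sequence and its raw number of reads. It closed with a normalized signal, which the authors computed as reads divided by alignments times 1 constant per library, as the deposited values show. Each alignment matched the deposited genome sequence exactly, and the stated number of alignments equalled the number of lines of every sequence. The constant was 1.11 units per read in the control and 2.51 in the mutant. It was 10000000 divided by a whole number, 9043954 in the control and 3986809 in the mutant, within 1.1e-08. These whole numbers were read as the library totals behind the authors' scaling. This reading is an inference from the values, and whether such a total counts all reads or mapped reads is not given in the sources used here.

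Raw reads were used as deposited for the main results, because the design was fixed that way before the data were examined. A sequence with several alignments was split evenly over them. The total of a 24-nt file is not the depth of its library, so the authors' scale and the reads of other lengths in the implied total stand beside the raw ratios as alternatives chosen after the files were seen. The organelle scaling used reads on the plastid and mitochondrial genomes, 14217 in the control and 22636 in the mutant. A read counted 0 times allows up to 3 reads, or 3.32 per 10000000 in the control and 7.52 in the mutant. The lower number of reads in the mutant makes its shares less precise.

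Nuclear chromosomes were divided into bins of 500 bp, and bins with at least 20 raw reads over both libraries were sorted by a 4-fold rule on the mutant-to-control ratio. Bins not over 4-fold lower are called kept. Strand shares used bins with at least 20 reads in the library and a limit of 90% on 1 strand. Pairing compared opposite-strand starts at the offset of a duplex with 2-nt 3′ overhangs against all other offsets within 12 nt. Phasing took the share of reads in the best of 24 registers, with minus-strand positions shifted by 2 nt, in bins with at least 10 positions, and set it against 1000 random placements. Intervals for single counts were exact Poisson, for shares exact Clopper-Pearson, and for ratios conditional binomial, at 95%. With 1 library per group no test, p-value or replicate check was made. Intervals on reads cover counting error only, since reads are PCR products without molecular identifiers. Intervals on shares or resamples of bins take bins as independent, although some lie close together, so they can be too narrow.

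The bins named were, by a rule fixed before the data were examined, the 5 with the most mutant reads among those with a ratio over 1. Bins named beyond this rule are said to be chosen after their values were seen. Other parts of the rule named protein-coding genes and microRNA genes. No annotation of the coordinates' build was used here, so gene bodies, 2 kb upstream regions, microRNA genes, structural RNA classes and the fixed gene lists were not analysed here, and no gene or list result is given. What lies at the named bins is not stated for the same reason.

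The bin comparison was tested on simulated data built from the control's bins. The phasing call was tested on invented bins, with most positions in 1 register or all placed at random. For the bin comparison over 24399 bins, 50 of 50 bins lowered 16-fold, 49 of 50 lowered 8-fold, 50 of 50 raised 8-fold and 50 of 50 raised 16-fold were recovered, and 1 of 24199 unchanged bins was put in a changed class. All 200 simulated phased bins and 0 of 200 unphased ones were called. As these bins were not drawn from the data, this does not show how the call performs on real bins. Alternatives covered the treatment of reads with several alignments, the read minimum, the bin width, the fold rule, the scaling, thinning of the control, the most abundant sequences, distinct sequences, and the phasing limit. Analyses were run with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.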

Results

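Small RNAs of 24 nt were measured by sequencing in young panicles, the developing flowering branches, of japonica rice. The design held 1 control library and 1 library of a mutant that the labels call the DES1 mutant and whose title carries the allele name osrdr2-3. RDR2 is the RNA-dependent RNA polymerase that copies plant transcripts into double-stranded RNA, from which Dicer-like 3 cuts 24-nt short interfering RNAs (siRNAs) that guide DNA methylation. The meaning of DES1 is not given in the sources used here, and taking the line as a mutant of RDR2 rests on the title. Whether the allele leaves any activity was not measured here. The comparison asks which 24-nt RNAs of the panicle are fewer in this mutant and which remain. The control library held 4701692 reads of 24 nt from 1514029 distinct sequences, and the mutant library 375564 reads from 103606 distinct sequences. No value has a replicate check, so no test between genotypes was made. The 95% intervals, exact Poisson, Clopper-Pearson or conditional binomial, compare these 2 libraries, not the genotypes. Those on reads cover counting error only. Those on shares of bins take bins as independent, although neighbouring bins can belong together, so they can be too narrow. Messenger RNA of the mutated gene is not measured in 24-nt reads, so the labels were not checked at the targeted gene.

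The 24-nt reads were far fewer in the mutant. The raw mutant-to-control ratio was 0.0799 (95% interval 0.0796 to 0.0801), a 12.5-fold lower number. On the authors' scale, per 10000000 of a library total, the 24-nt reads came to 5198713 in the control and 942017 in the mutant, a 5.52-fold lower level (5.50 to 5.54). Reads of 24 nt made up 51.99% (51.95 to 52.02) of the total implied by that scale in the control and 9.42% (9.39 to 9.45) in the mutant. Scaled instead to the reads of all other lengths in that total, 4342262 in the control and 3611245 in the mutant, the 24-nt reads were 10.4-fold lower. With reads that align to 1 place only the raw ratio was 0.0494 (0.0492 to 0.0496), and scaled to reads on the organelle genomes it was 0.0502 (0.0500 to 0.0503).

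The fall ran along all 12 nuclear chromosomes. Chromosome 1 had the lowest raw ratio, 0.0403 (0.0398 to 0.0408), and chromosome 10 the highest, 0.196 (0.194 to 0.197), followed by chromosome 4 at 0.133 (0.131 to 0.134). Of 380 windows of 1 Mb, 378 held fewer raw reads in the mutant, and 368 were lower on the authors' scale. The median window held 7764 reads per 10000000 in the control and 1255 in the mutant. The window with the highest ratio, starting at position 10000001 of chromosome 10, held 13811 control and 21840 mutant reads, a raw ratio of 1.58. A single 500 bp bin in it, starting at 10320501, held 2277 of these control and 8731 of these mutant reads. In that bin 1 sequence made up 84.7% of mutant reads. The window starting at 9000001 of chromosome 4 came next with 12395 and 17159 reads, a ratio of 1.38. Both windows were chosen after their values were seen.

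**Figure D1:**
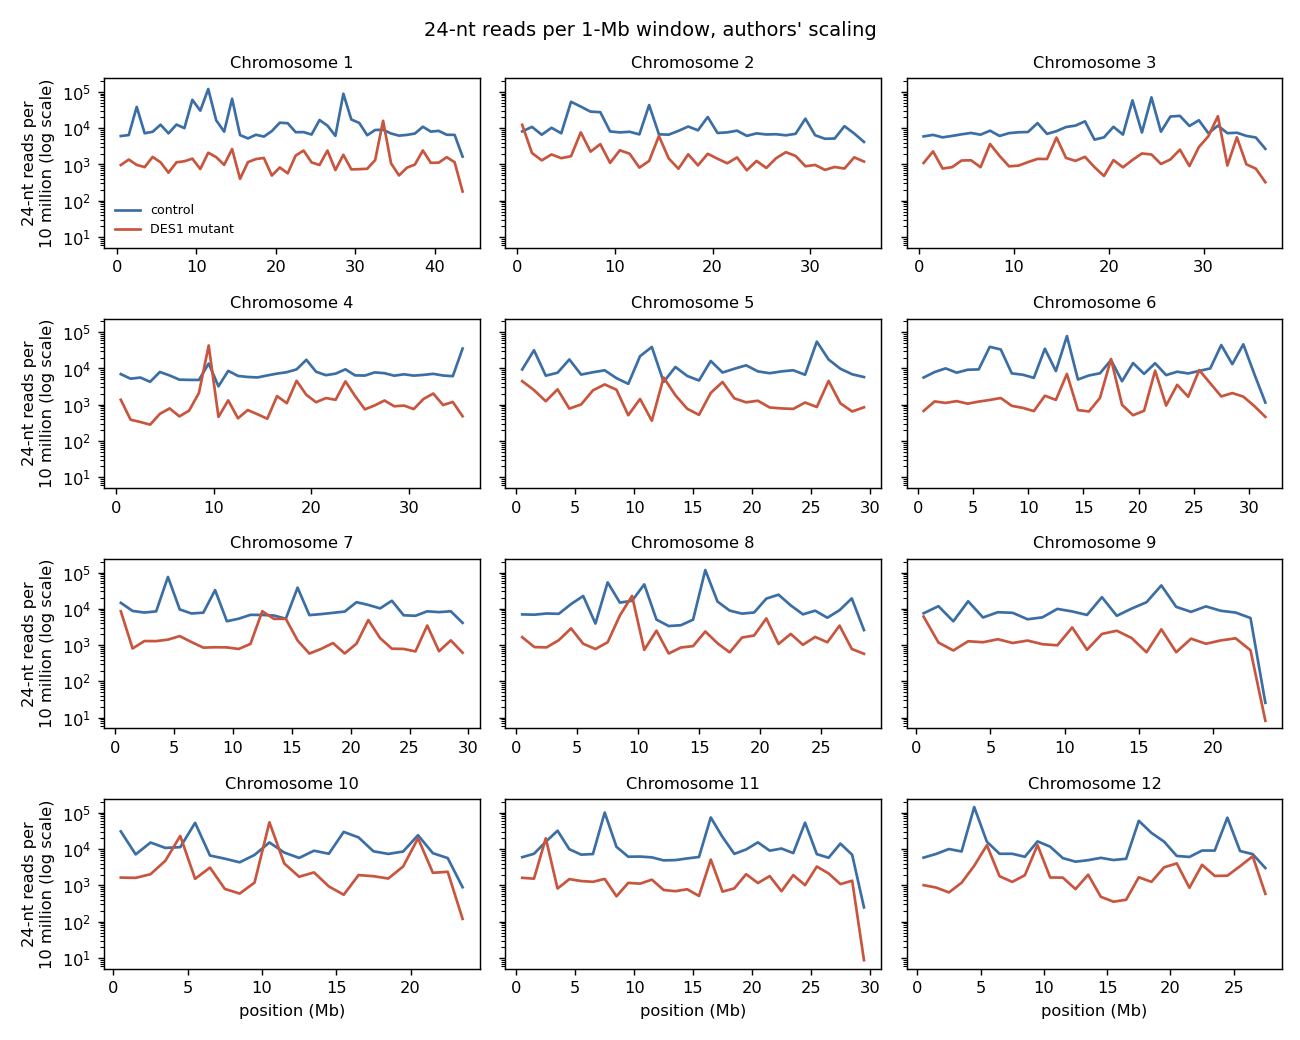
Lines give 24-nt reads per 1-Mb window along the 12 nuclear chromosomes, in reads per 10000000 on the authors' scale (log axis), with position in Mb, for the control (blue) and DES1 mutant (red) library. The mutant line lies under the control line in 368 of 380 windows.

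Reads on the organelle genomes did not fall. Reads on the plastid genome numbered 8962 in the control and 16014 in the mutant (raw ratio 1.79, 1.74 to 1.83), and their share of 24-nt reads was 0.191% in the control and 4.26% in the mutant. The mitochondrial genome held 5255 and 6621 reads, a raw ratio of 1.26 (1.22 to 1.31). Most of these organelle reads have more than 1 alignment, and among reads of 1 alignment the share on both organelle genomes together was 0.00981% in the control and 0.259% in the mutant. Nuclear reads made up 99.7% of the control and 94.0% of the mutant reads. Sequences with any organelle alignment, many of which also align to the nuclear genome, took 1.38% of control reads and 29.5% of mutant reads (raw ratio 1.70, 1.69 to 1.72), and sequences with none had a raw ratio of 0.0571 (0.0569 to 0.0573). The telomere repeat, counted as 62 control and 47 mutant reads, had a raw ratio of 0.758 (0.508 to 1.13) and a ratio of 1.72 (1.15 to 2.55) on the authors' scale, so its direction depended on the scaling.

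The make-up of the 24-nt reads differed between the libraries. Reads starting with A, the 5′ nucleotide that the Argonaute proteins of RNA-directed DNA methylation prefer, made up 56.6% (56.5 to 56.6) of control reads and 39.8% (39.7 to 40.0) of mutant reads. With every alignment of a sequence counted, the shares were 51.8% and 49.4%, a much smaller gap. Reads starting with T (U in the RNA) made up 17.1% and 28.6%. Reads aligning to 1 place made up 77.0% of the control and 47.6% of the mutant, and reads aligning to 6 to 20 places 5.73% and 30.0%. Of the 63013 sequences with at least 10 control reads, 4328 (6.87%) were seen in the mutant. The 100 most abundant sequences of each library held 2.80% of control reads and 28.0% of mutant reads.

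**Figure D2:**
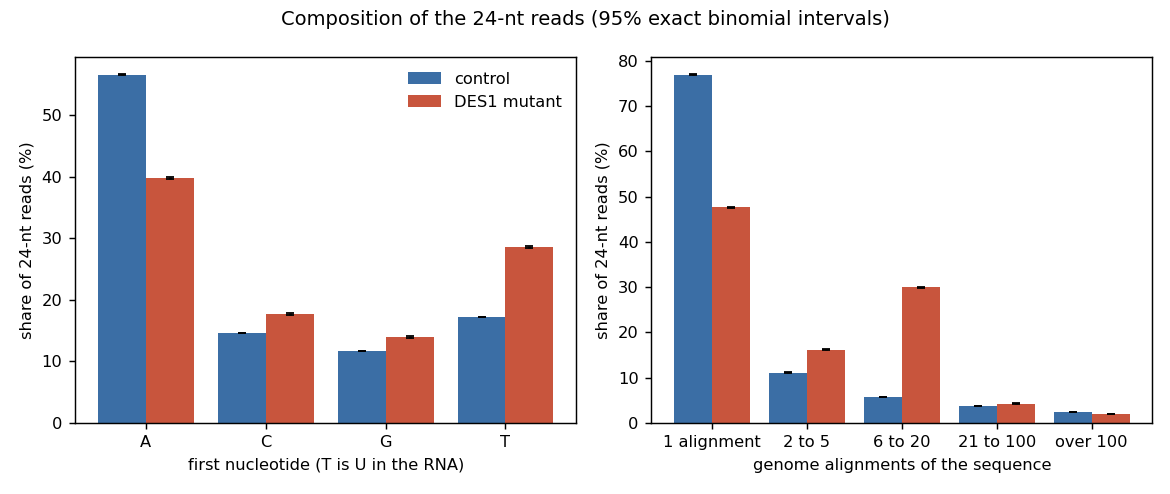
Bars give the share of 24-nt reads, in percent, by first nucleotide (left) and by number of genome alignments of the sequence (right) in the control (blue) and DES1 mutant (red) library, with 95% exact binomial intervals. Reads starting with A are 56.6% and 39.8% (51.8% and 49.4% with every alignment counted, not drawn), and sequences with 6 to 20 alignments go from 5.73% to 30.0%.

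The loss covered most loci that held 24-nt reads. Of 26493 nuclear bins of 500 bp with at least 20 raw reads over both libraries, 23737 (89.6%) had over 4-fold fewer reads in the mutant, 2299 (8.68%) lay within 4-fold, and 457 (1.72%) had over 4-fold more. The mutant had no read in 14039 bins (52.99%). The 584 bins with at least 1000 control reads held 39.3% of all control nuclear reads, and 570 of them were over 4-fold lower. The median over the 584 was 1259-fold lower in raw reads. This fold is imprecise, since lost bins with at least 1000 control reads of 1 alignment held a mean of 2.74 such mutant reads. Those few reads may be carried over from the control library, which could not be told apart here, so the fold may understate the fall. The 95% interval of the ratio lay wholly under 0.25 in 22217 bins and wholly over 4 in 84. On the authors' scale 23253 bins were lower and 1370 higher. With each library scaled to its own 24-nt reads, which removes the overall loss on the same bins, 20762 were lower and 2647 higher, so that 11.3% of the bins past 4-fold were higher, against 1.89% with raw reads. With the control thinned to the mutant's number of reads, which also left only 3120 bins over the read minimum, 1357 were lower and 1748 higher (56.3%).

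The 5 bins with the largest fall in reads were chosen after their values were seen. On chromosome 12, the bin from 24731001 to 24731500 held 14336 control and 5 mutant reads, a ratio of 0.000349 (0.000113 to 0.000814). At chromosome 11, 16333001 to 16333500, reads numbered 13163 and 9. A pair of nearby bins on chromosome 8 held 12682 and 12 reads (15459501 to 15460000) and 12479 and 13 reads (15457501 to 15458000). On chromosome 3, the bin from 22408501 to 22409000 held 11593 and 14 reads. In these 5 bins the control reads came from both strands and from 477 to 571 alignment positions each.

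**Figure D3:**
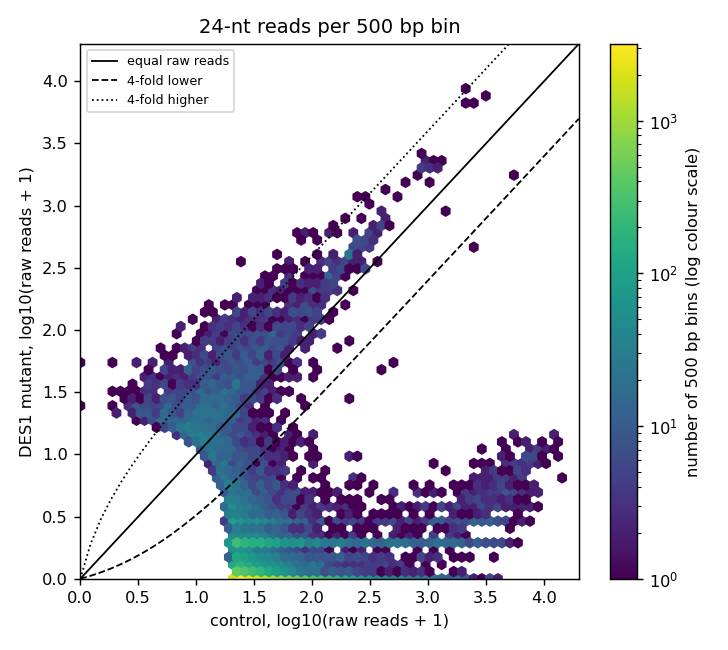
Each hexagon counts 500 bp nuclear bins (log colour scale) by raw 24-nt reads in the control (x axis) and DES1 mutant (y axis), both as log10(reads + 1), for the 26493 bins with at least 20 reads over both libraries. Most bins lie under the 4-fold line near 0 mutant reads, and a smaller group lies along or above the line of equal reads.

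A smaller set of loci kept or gained 24-nt reads. The 2756 bins (10.4%) that were not over 4-fold lower held 2.74% of control nuclear reads and 71.0% of mutant nuclear reads. Bins were chosen on the reads of both libraries together, so many kept bins passed the minimum through their mutant reads. At least 20 control reads were held by 1085 of the kept bins and by 23314 of the 23737 lost bins, so on control reads alone the kept share is lower. The 5 bins with the most mutant reads among those with a ratio over 1 each produced reads from 1 strand almost alone, with 1 sequence at 70.2% to 94.3% of the mutant reads. At chromosome 10, 10320501 to 10321000, reads numbered 2277 in the control and 8731 in the mutant, a raw ratio of 3.83 (3.66 to 4.02), and 7395 of the mutant reads were the sequence GAAATGATCTTGGACGTAATCTAG at 10320914 to 10320937 on the minus strand, which aligns to 1 place. At chromosome 11, 2523001 to 2523500, they numbered 2133 and 6709, a ratio of 3.15 (3.00 to 3.30). The bin at chromosome 7, 12756001 to 12756500, held 910 and 2782 reads, a ratio of 3.06 (2.84 to 3.30). A second bin on chromosome 10, 4833501 to 4834000, held 3061 and 7431 reads (2.43, 2.33 to 2.53), and the bin at chromosome 6, 17505501 to 17506000, held 2663 and 6389 (2.40, 2.29 to 2.51). On the authors' scale these ratios were 8.70, 7.14, 6.94, 5.51 and 5.44. For the chromosome 6 bin, reads aligning to 1 place gave a ratio of 0.25 (0.00508 to 2.53), from few reads. Its main sequence aligns to 2 places, and its 5001 control and 12054 mutant reads were split evenly over them. By its share of reads in each bin, the other place lies in the second chromosome 10 bin. These 2 bins thus mostly count the same reads and are not separate gains. At that chromosome 10 bin, reads aligning to 1 place gave 2.88 (2.48 to 3.36).

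Bins with reads from 1 strand took a larger share in the mutant. Among bins with at least 20 reads in the library, over 90% of reads lay on 1 strand in 2724 of 24399 control bins (11.2%, 10.8 to 11.6) and in 1004 of 1692 mutant bins (59.3%, 57.0 to 61.7). With every alignment counted these shares were 8.91% and 24.8%. In the control library itself, the share on 1 strand was 59.6% (56.6 to 62.6) for bins kept in the mutant and 8.91% (8.55 to 9.28) for bins lost in it. Duplexes cut by a Dicer leave 2-nt overhangs at their 3′ ends. An opposite-strand partner at that offset was found for 24.7% of control nuclear reads, against a median of 21.7% over the other offsets within 12 nt, and the share at offset 0 was higher still, 26.1%. With the control thinned to the mutant's number of reads, the shares were 8.23% and 7.24%. In the mutant 4.71% (4.64 to 4.78) of reads had a partner at the 2-nt offset, against a median of 1.996%, a 2.36-fold excess compared with 1.14-fold in the thinned control. By class, the excess was 2.27-fold in the thinned control and 2.80-fold in the mutant for kept bins, and 1.13-fold and 1.23-fold for lost bins. Kept bins held 10342 thinned control reads and 250512 mutant reads, so this comparison is not matched in depth. They include all 85 bins phased in the mutant, whose choice itself joins the strands at the 2-nt offset. Without these 85 bins, the mutant's excess over all other nuclear reads was 1.39-fold.

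**Figure D4:**
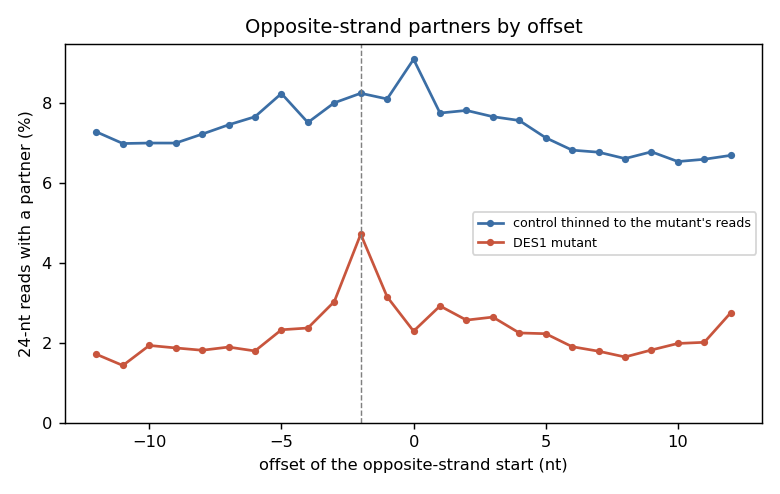
Points give the percent of 24-nt nuclear reads with an opposite-strand partner at each offset from -12 to 12 nt, for the control thinned to the mutant's reads (blue) and the DES1 mutant (red), and the dashed line marks the 2-nt overhang. The mutant has its peak there, 4.71%, and the thinned control has its highest value at offset 0, 9.08%.

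Phased 24-nt siRNAs, cut one after another from a long double-stranded precursor so that their ends share 1 of 24 registers, are known from reproductive tissue as a class made through another RNA-dependent RNA polymerase, and the bins called phased in both libraries held more reads in the mutant. By the rule that at most 1 of 1000 random placements reached the observed share, 85 of 1404 bins were phased in the mutant. There, 1 in 1000 bins is 1.40. In the control 50 of 23400 were, where 1 in 1000 bins is 23.4. The rule lets 1 placement reach the observed share, so chance can give more than these numbers. By number alone the control's 50 calls are therefore not clearly above chance, unlike the mutant's 85, although 26 of the 50 were called in the mutant too. Of these 50 bins, called on control reads alone, 27 (54%, 39.3 to 68.2) had more raw reads in the mutant, against 2.84% (2.63 to 3.06) of the unphased bins tested in the control. Of those 23350 unphased bins 22441 were over 4-fold lower, so this contrast mostly sets kept against lost bins. The 50 bins had a pooled ratio of 2.11 (2.03 to 2.19), 4.79 on the authors' scale and 1.32 scaled to organelle reads. The 26 bins phased in both libraries, which had to be well covered in the mutant to be called, held 1643 control and 8529 mutant reads, a ratio of 5.19 (4.92 to 5.48), and all 26 were higher in the mutant. Unphased bins that passed the same filter on mutant reads pooled to a ratio of 2.08 (2.06 to 2.10), and 1249 of 1319 were higher in the mutant. Without bins of mostly organelle sequence, the ratio was 2.28 (2.25 to 2.31), and 933 of 999 were higher. The bin at chromosome 5, 17802001 to 17802500, held 242 and 1100 reads (ratio 4.54, 3.94 to 5.24). The bin at chromosome 6, 25517001 to 25517500, held 152 and 739 reads (4.85, 4.07 to 5.81), and that at chromosome 2, 6001501 to 6002000, held 92 and 624 (6.78, 5.44 to 8.54). The bin at chromosome 4, 18234001 to 18234500, held 70 and 603 (8.61, 6.71 to 11.2). These 4 bins were chosen by mutant reads after their values were seen. Another 24 bins were phased in the control alone, no more than chance can give, and 23 of them were over 4-fold lower in the mutant.

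**Figure D5:**
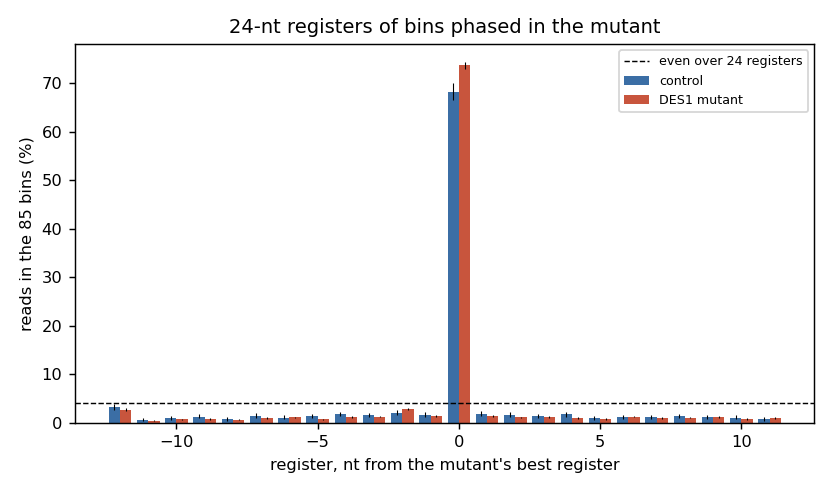
Bars give the percent of 24-nt reads in each of 24 registers, counted in nt from the register with the most mutant reads of each bin, pooled over the 85 bins phased in the mutant, with 95% exact binomial intervals, for the control (blue) and DES1 mutant (red). The register was chosen as the one with the most mutant reads, of which it holds 73.6%, and the same register holds 68.2% of control reads, against 37.3% of control reads in the 1319 unphased bins tested in the mutant. The dashed line marks an even spread.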

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

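The scalings by the authors' constants, by reads of other lengths and, for the library totals, by organelle reads, and the removal of organelle-aligning sequences, were chosen after seeing the data. No paired analysis was possible because each group has 1 library, and leaving out a replicate was not possible for the same reason. The alternatives set for reads at genes and for gene lists were not run, because no annotation of the build was used here, and the reference scaling used organelle reads without structural RNA genes. The fall of 24-nt reads held under each alternative run. The raw ratio of 0.0799 moved to 0.0684 with distinct sequences, 0.0494 with reads of 1 alignment, 0.0593 without the 100 most abundant sequences of each library, 0.181 with the authors' constants, 0.0960 with reads of other lengths, 0.0502 with organelle reads and 0.0571 without organelle-aligning sequences. Every read matched the aligned genome sequence exactly, so that alternative moved nothing. The organelle share, 0.302% in the control and 6.03% in the mutant, moved to 0.00981% and 0.259% with reads of 1 alignment, 0.238% and 4.06% with every alignment counted, and 0.240% and 3.65% for distinct sequences. The share starting with A moved to 57.2% and 41.0% with reads of 1 alignment, to 51.8% and 49.4% with every alignment counted, which narrowed the gap to a few points, and to 56.9% and 45.3% without organelle-aligning sequences. Lower bins, 23737, moved past 1.5 times to 198911 with every alignment counted, 116289 with a minimum of 5 reads, 2884 with a minimum of 100 and 1357 with the thinned control. These settings change how many bins are tested (219655, 127820, 3528 and 3120). Higher bins, 457, moved past 1.5 times to 842, 1262, 120 and 1748 under those settings, and to 2647 with each library scaled to its own 24-nt reads, 200 with organelle scaling, 1109 with the 2-fold rule and 1370 with the authors' constants. Bins on 1 strand moved to 12.5% and 54.9% with reads of 1 alignment and to 8.91% and 24.8% with every alignment counted. Pairing at the 2-nt offset moved to 26.2% and 5.87%, and to 26.98% and 11.8%. Phased bins in the control moved from 50 to 147 at the 99th percentile, where 10 in 1000 bins is 234. They moved to 31 with positions counted once, so single calls in the control are weak. In the mutant they were 115 and 79. For the named bins, 1 value changed direction, the chromosome 6 bin at 17505501, with a ratio of 0.25 for reads of 1 alignment, where the main sequence of the bin aligns to 2 places and drops out. Another 16 values of named bins moved and 23 did not. Of the 26493 bins, 22936 held fewer than 3 mutant reads, so their ratios are imprecise.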

Other observations

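Beyond the report, the mutant's reads were gathered in fewer places. Bins holding 50% of nuclear reads numbered 2007 in the control and 374 in the mutant. Some of the bins phased in the mutant lay close together: 7 on chromosome 12 from 22729001 to 22788000 with 100 control and 712 mutant reads, 6 on chromosome 2 from 6001001 to 6034500 with 243 and 1306 reads, 4 on the same chromosome from 6840001 to 6859500 with 181 and 830 reads, and 4 on chromosome 10 from 11842501 to 11873000 with 267 and 1142 reads. The 85 bins phased in the mutant held 4.14% of mutant and 0.0640% of control nuclear reads, and 84 of them had more raw reads in the mutant, as did 1249 of 1319 unphased bins that passed the same filter on mutant reads, so this count owes much to the choice of bins. The most abundant mutant sequence, TCCTAACGAACGAACGATTTGAAC, aligned to 13 places, 1 of them on chromosome 1 at 33588456 to 33588479, and had 6616 control and 16310 mutant reads. It is shared with an organelle genome. In the bin of that place, 33588001 to 33588500, it made up 57.7% of mutant reads, and organelle-aligning sequences made up 99.5%.

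Of the tests below, those on organelle sequence, on perfect inverted repeats, on carried-over reads and on phased bins were chosen after the result or a part of it was seen, and the others were set before.

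At 2756 bins 24-nt reads were kept in the mutant. With reads of 1 alignment only, 8.07% of bins were kept, near the 10.4% with split reads, which argues against multi-mapped reads as the whole source, although the number kept went from 2756 to 1433 and 50.03% of mutant reads in kept bins aligned once, against 88.8% of control reads in lost bins. Sequences shared with the organelle genomes made up 32.8% of the mutant reads in kept bins, between the limits set at 50% and 10%, and most of the reads in 16.4% of kept bins (15.1 to 17.9), so they account for part of the pattern and not for most bins. Single-stranded or hairpin precursors, which need no RNA-dependent polymerase, are a candidate explanation: among bins with 20 to 200 control reads, kept bins lay on 1 strand in the control more often than lost bins by 45.8 percentage points, and 45.7% (42.2 to 49.3) still did after bins of mostly organelle sequence were left out, against 9.30% of lost bins. Sequences with an opposite-strand copy within 3000 bp made up 1.65% of mutant reads in kept bins, which argues against hairpins of perfect inverted repeats as the main source, so that single-stranded precursors, imperfect hairpins and fragments of abundant RNAs stay open.

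Of the 50 bins called phased on control reads alone, 54% (39.3 to 68.2) were higher in the mutant, against 2.84% of unphased bins. Mutant reads played no part in this call, which argues against the choice of bins with many mutant reads as the whole cause. The contrast does not tie the rise to phasing, because 22441 of the 23350 unphased bins were over 4-fold lower. The pooled ratio of the 50 bins scaled to reads of other lengths was 2.54 (2.44 to 2.63), above the range set for the loss of other 24-nt reads from the total. Scaled to organelle reads it was 1.32, inside that range, so the answer depends on the scaling. The pool also mixes 27 bins higher in the mutant with 23 over 4-fold lower. Whether the rise was shared with all other kept bins was not settled. Among kept bins, the 27 phased in the control had a median ratio of 4.85. It was 1.36 for 638 unphased bins tested in the control, without those of mostly organelle sequence. The first median was 3.57 times the second (3.11 to 4.52 over 10000 resamples of bins). Kept bins are chosen by this same ratio, which left out 23 of the 50 bins phased in the control, so the comparison cannot decide. The bins phased in the mutant stood at a median of 1.79 times the ratio of unphased bins with similar mutant reads, and 72 of the 85 lay above the median of their matched bins. Phasing in the mutant alone is argued against, since of 42 mutant-phased bins that could be tested in the control 26 (61.9%, 45.6 to 76.4) were phased there too, against 0.214% of all bins tested in the control. Greater use of proteins freed by the loss of other precursors may explain the rise, and so may panicles at another stage. Neither was tested, and with 1 library per genotype both stay open.

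Few reads remained at the lost loci. At 535 lost bins with at least 1000 control reads of 1 alignment, 1464 mutant reads stood against 1702459 control reads, a ratio of 0.000860, and their dispersion around that single proportion was 1.20 (1.07 to 1.36), slightly over the 0.882 to 1.14 of 2000 simulated draws. Reads carried over from the control library may be the source at these bins, where 96.3% of the reads were sequences also seen in the control, but they cannot be told apart from a small, nearly uniform remainder of siRNA production. Counted on reads of 1 alignment, the other 22137 lost bins with such reads had a ratio of 0.00354 (0.00343 to 0.00365), 4.11 times as high, which argues against the same proportion of carried-over reads as the whole source there. Over all reads at lost bins, the share starting with A was 55.9% (54.9 to 56.9) in the mutant and 56.8% in the control. This mutant-minus-control difference of -0.89 percentage points argues against unspecific fragments as the main source. For reads of 1 alignment the shares were 52.8% (51.4 to 54.1) and 56.9%, a difference of -4.11 points whose interval passes the limit set. Mutant reads there also differed otherwise: 5.62% against 0.0203% of control reads aligned to an organelle genome, and 56.4% against 88.8% had 1 alignment. Such fragments may thus be part of the source.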
